A study of Oryza sativa Japonica Group with 24 samples.

How the data were processed

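The signals were single-color (Cy3) readings of 24 oligonucleotide arrays, deposited both as scanner output of Agilent Feature Extraction 10.5.1.1 and as a series matrix. According to the file headers, the deposited intensity values had been background subtracted, corrected for spatial trends and for effects within the array, and not scaled between arrays. The log2 values of the series matrix, as the authors deposited them, were log2 signals minus the 75th percentile of all spots of each array, without centering by gene. Each array held 45151 spots, of which 1417 were manufacturer controls and 590 controls of the array design, and 43144 gene spots covered 42418 probes and 29690 loci. For 510 probes no locus was given, and 7801 loci had several probes.

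The log2 of the deposited processed intensity was taken, and the 75th percentile of the gene spots of each array was subtracted. Spots marked as outliers by the scanner software were left out, and spots of the same probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group. A locus with several probes was represented by its probe with the highest mean signal over all arrays. Control spots were left out, since they match no rice gene. The median processed signal per array ran from 869 to 1432 intensity units, and precision came from the 3 arrays of each group. The filter left 25513 genes, 25303 of them tied to a locus and 210 probes without a locus, and 25357 had a value on every array.

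Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 coefficient for each of the 8 groups and all 24 arrays in the fit, which left 16 residual degrees of freedom and 1.83 prior degrees of freedom. Contrasts were each deficiency against the control of its time, deficiencies against each other within a time, the control at 24 h against 6 h, and the difference of each deficiency effect between times. Values of p were adjusted by Benjamini and Hochberg over the genes of each contrast, a gene was called at an adjusted p under 0.05, and a second count required at least a 2-fold change. Errors beside fold changes are standard errors of the fit. When the dimmer group was well above background on none of its arrays, the fold was replaced by a lower bound from the background level. The bound used the mean of the brighter group, and is no secure minimum where some of that group's arrays were not well above background. Data were read with Python 3.11.15, numpy 2.4.6 and the package data.table (version 1.17.8), and drawn with matplotlib 3.10.9.

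For gene groups 30 lists were tested, 17 of loci and 13 matched to gene descriptions. The 17 lists held 192 loci with symbols written from general knowledge of rice, of which 4 loci were absent from the array. Lists were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 180 tests of 30 lists and 6 contrasts, and again with the correlation estimated from the residuals and with fry. Other contrasts had their own adjustment over 30 lists. A set test used only genes with a value on every array. For each list the calls were also counted after adjustment over the list alone.

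Genes were named by a rule. Per deficiency contrast the 10 largest rises and 10 largest falls were ranked among called genes with an informative description whose arrays of 1 group all lay above those of the other, and whose probe was well above background in the brighter group. Per list and contrast up to 4 members with the smallest adjusted p were added, and the text names genes from the top of each ranking. For contrasts between deficiencies and for time differences the 5 largest each way were ranked. Except for time differences, a gene that lacked a value on an array of either group was not ranked.

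The tests, thresholds, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were normexp background correction with offset 50, quantile normalization, series matrix values, no filter or a filter on all 24 arrays, the mean of the probes of a gene, outlier marks ignored, slide as a random or fixed block, the replicate number as a block, only the arrays compared in the fit, eBayes with trend and robust setting, and each array left out in turn. The comparison with the mean of the other 2 deficiencies and the fit without 3 arrays were added after the data were seen. Replicate numbers did not pair arrays: residuals of arrays with the same number had a mean correlation of -0.0091 over 84 pairs. The code was tested on simulated data with 200 changed genes: 66%, 88%, 94% and 96% of 50 genes each were recovered at log2 changes of 0.5, 1, 2 and 3. In that test 12 unchanged genes were called, and 1 of 180 list tests, the list that had been shifted.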

Results

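Transcript levels were measured in roots of rice seedlings (Oryza sativa Japonica Group, cultivar Nipponbare) on 24 single-color oligonucleotide arrays. The arrays form 8 groups of 3 replicates: a complete nutrient solution (control) and solutions without ammonium nitrate (-N), without sodium phosphate (-P) or without potassium sulfate (-K), each 6 h and 24 h after the change of solution. The share of gene spots with a signal well above background was 81.6% ± 4.55 (SD, n = 24) per array, from 73.2% to 90.3%, and the number of arrays sets the precision. Replicates of a group had correlations across genes between 0.990 and 0.997, where genes are not independent replicates. Values given for a gene are log2 fold changes with the standard error of the limma fit. They come from 3 arrays against 3 where no value was left out as an outlier. The digits between Os and g in a locus name give the chromosome; genome positions were not used here. Where no array of 1 group was well above background, an "at least" fold is given in place of a fold, and a group well above background on only 1 or 2 of its arrays is named. Rises and falls called largest are those of a ranking of called genes with an informative description. In these genes every array compared had a value, and the arrays of 1 group all lay above those of the other. Their probe was well above background on all arrays of the brighter group.

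The file headers gave 2 scan days. The 15 arrays of day 1 were all 6 h arrays and the 24 h controls, and the 9 arrays of day 2 were the -N, -P and -K arrays of 24 h. Gene spots well above background made up 78.6% ± 2.44 (SD, n = 15) on day 1 and 86.7% ± 1.97 (SD, n = 9) on day 2, and the median local background was 48.8 ± 2.89 and 23.5 ± 0.791 intensity units. Comparisons at 6 h and comparisons between deficiencies at 24 h stayed within 1 scan day. Each comparison of a deficiency with the control at 24 h set day 2 against day 1, so that scan day and deficiency cannot be told apart in it. Random-sequence probes, which match no rice gene, were well above background for 1.67% of probes in the 6 h controls and 2.5% in the 24 h controls, against 30.6%, 26.9% and 36.4% under -N, -P and -K at 24 h. The arrays -N replicate 1, -P replicate 2 and -K replicate 2 of 24 h stood apart with 38.3%, 46.7% and 70.8%. All changes are relative to the 75th percentile of the gene spots of an array. On that scale 7 bright spike-in controls had median shifts against the control of -0.31, -0.13 and -0.21 under -N, -P and -K at 6 h and -0.56, -0.50 and -0.52 at 24 h. Splits into higher and lower genes and small changes depend on this choice of scale.

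**Figure D1:**
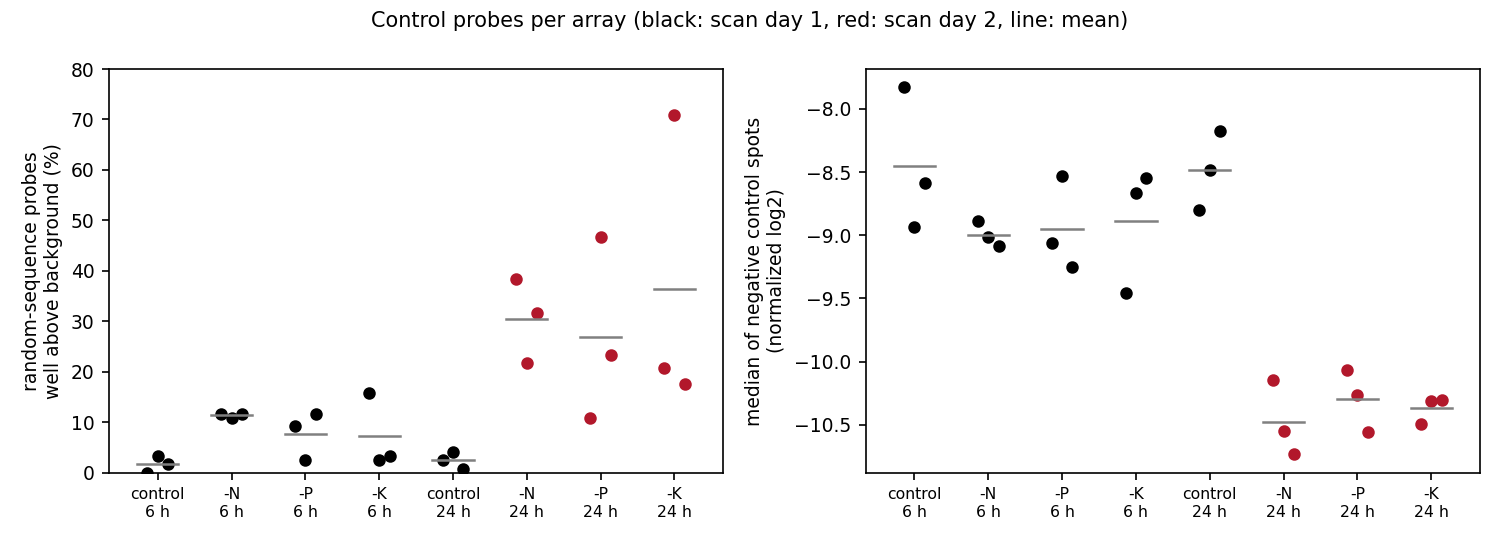
Control probes on each of the 24 arrays, by group: percent of random-sequence probes well above background (left) and median normalized log2 signal of the negative control spots (right). Points are arrays (black for scan day 1, red for day 2) and lines are means of 3 arrays, and the day 2 arrays had the lowest negative control medians, and -K replicate 2 of 24 h had the highest share of random-sequence probes, 70.8%.

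The comparison of -N with the control at 6 h asked which root transcripts had changed within 6 h of nitrogen removal. Of 14 tested members of the nitrate uptake and reduction list, 11 were higher, 1 was lower and 2 were not called (11 and 2 adjusted over the list alone). OsNRT2.1 (Os02g0112100), a high-affinity nitrate transporter well above background on 2 of 3 control arrays, was higher by 8.25 ± 0.29, OsNRT2.2 (Os02g0112600) by 3.41 ± 0.12 and OsNRT2.3 (Os01g0704100) by 3.29 ± 0.09. The list exceeded other genes by camera (adjusted p = 1.09e-06, and adjusted p = 0.053 with an estimated correlation). Of 13 genes that assimilate ammonium into amino acids 7 were lower, 3 higher and 3 not called (7 and 3 adjusted over the list alone; camera adjusted p = 0.00946, and adjusted p = 0.168 with an estimated correlation). Asparagine synthetase OsASN1 (Os03g0291500) changed by -4.97 ± 0.10, alanine aminotransferase OsAlaAT (Os10g0390500) by -1.92 ± 0.09 and the root glutamine synthetase OsGS1;2 (Os03g0223400) by -1.15 ± 0.08. Ammonium transporters went both ways, with 4 of 9 higher, 3 lower and 2 not called. OsAMT1;2 (Os02g0620500) was higher by 2.67 ± 0.13 and OsAMT3;3 (Os02g0550800) by 2.51 ± 0.10, and OsAMT2;2 (Os01g0831300) changed by -1.98 ± 0.10.

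Under -N at 6 h the non-symbiotic haemoglobins OsHB2 (Os03g0226200) and OsHB1 (Os03g0233900) changed by -2.15 ± 0.28 and -1.62 ± 0.19. Of 14 iron deficiency response genes, which serve iron uptake and its regulation, 8 were lower, 1 was higher and 5 were not called (8 and 1 adjusted over the list alone). The small peptide gene OsIMA1 (Os01g0647200) changed by -1.59 ± 0.20 and the regulator OsIRO3 (Os03g0379300) by -0.65 ± 0.09. This list call (camera adjusted p = 0.0137, and adjusted p = 0.529 with an estimated correlation) ended with quantile normalization (0.126) and with normexp background correction (0.0914). Ribosomal protein genes were lower in 83 of 298, higher in 12 and not called in 203 (73 and 11 adjusted over the list alone), among them the plastid-specific Os03g0856500 at -1.55 ± 0.20. Their call (camera adjusted p = 0.000235, and adjusted p = 0.748 with an estimated correlation) ended with normexp (0.102). Of 12 phosphate signalling genes 4 were higher and 3 lower, with OsSPX-MFS2 (Os02g0678200), well above background on 2 of 3 -N arrays, at -2.27 ± 0.15. Of 12 phosphate transporters 1 was higher and 4 lower, with OsPHO1;3 (Os06g0493600) lower. Its bound of 2.64-fold is no secure minimum, since only 2 of 3 control arrays were well above background. Among 9 photosynthesis genes, taken as markers of shoot tissue, 1 was called: OsPSBO (Os01g0501800) at -1.28 ± 0.41. That call ended without -N 6 h replicate 1 (-0.92), without -N 6 h replicate 3 (-1.12), with the mean of its probes (-0.96) and with only the arrays compared.

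The largest ranked changes under -N at 6 h outside those groups were rises of a probe for the microRNA precursor osa-miR166m (4.75 ± 0.15), of a gene with a heavy metal transport domain (Os04g0401000, 4.18 ± 0.28) and of an In2-1 protein gene (Os03g0283200, at least 7.39-fold). The gene Roc1 (Os04g0627000) had a rise of similar size but was not ranked, since only 2 -N arrays had a value. Its mean was -1.01 under -N and -5.76 in the control, where 2 of 3 arrays were well above background. The largest falls included the glycolytic aldolase C-1 (Os08g0120600, -4.68 ± 0.24), a rhodanese-like gene (Os12g0428000, -4.30 ± 0.16) and a Bowman-Birk trypsin inhibitor (Os03g0823400, -3.78 ± 0.19). By limma 10731 of 25491 genes were called, 5712 higher and 5019 lower, and 1323 changed at least 2-fold, 661 higher and 662 lower. Normexp background correction gave 5056 higher and 7709 lower, and 313 and 518 at 2-fold. The -N, control and other 6 h arrays mostly sat on slides of their own, so that slide could not be a fixed term here.

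**Figure D2:**
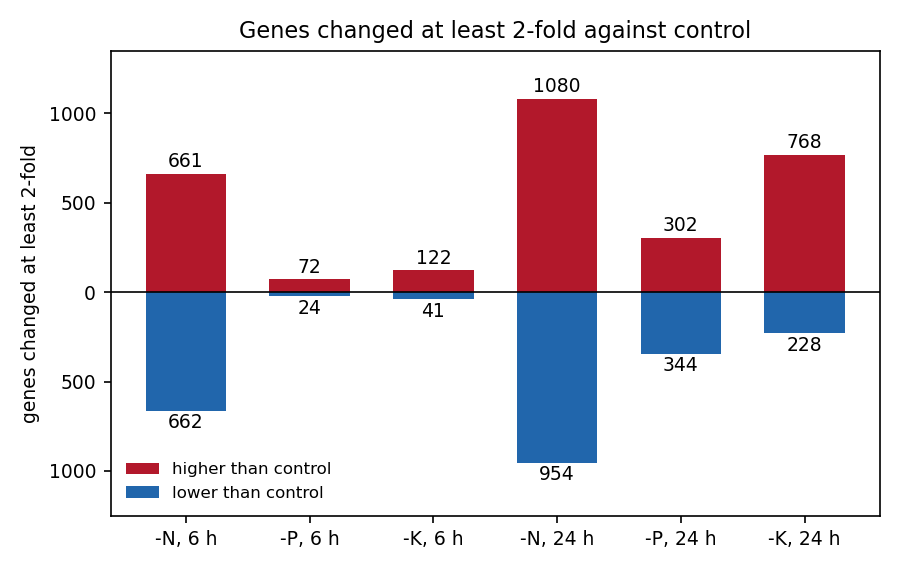
Genes called by limma with at least a 2-fold change against the control of the same time, for each deficiency and time. Red bars count genes higher than control and blue bars genes lower, and the highest counts were under -N at 24 h, 1080 higher and 954 lower, and the fewest under -P at 6 h, 72 and 24.

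The comparison of -P with the control at 6 h asked the same of phosphorus removal. Of 14 iron deficiency response genes 6 were lower and 8 were not called (12 lower adjusted over the list alone). OsIMA1 (Os01g0647200) changed by -1.30 ± 0.20, the iron transporter OsIRT2 (Os03g0667300) by -1.07 ± 0.12 and the regulators OsIRO2 (Os01g0952800) and OsIRO3 (Os03g0379300) by -0.82 ± 0.13 and -0.81 ± 0.09. The iron list call held both ways (camera adjusted p = 2.69e-13, and adjusted p = 0.0422 with an estimated correlation). Ferritins OsFER1 (Os11g0106700) and OsFER2 (Os12g0106000) were higher, OsFER1 by 1.07 ± 0.07 and OsFER2 2.15-fold. Their set test (adjusted p = 0.00016) rested on OsFER2 alone, since OsFER1 lacked a value on 1 array. Glutathione S-transferases, which conjugate glutathione to toxic compounds, were higher in 16 of 59 and not called in 43 (23 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.91e-08, and adjusted p = 0.0166 with an estimated correlation). Examples were Os01g0949800 (1.36 ± 0.20), Os01g0353400 (1.33 ± 0.16) and Os01g0369700 (1.14 ± 0.13).

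Cytokinin response regulators and oxidases were called as a list under -P at 6 h, with 2 of 9 higher and 7 not called (4 higher adjusted over the list alone; camera adjusted p = 0.00108, and adjusted p = 0.0367 with an estimated correlation): the type-A response regulators OsRR9 (Os11g0143300, 0.54 ± 0.09) and OsRR10 (Os12g0139400, 0.47 ± 0.08). Of 13 ammonium assimilation genes 3 were lower and 10 not called (6 lower adjusted over the list alone; camera adjusted p = 0.00177, and adjusted p = 0.0787 with an estimated correlation). Of 12 phosphate signalling genes 2 were higher and 10 not called, with a median of 0.08 that became -0.03 with normexp. Of 12 phosphate transporters 1 was higher, and neither list was called (camera adjusted p = 0.456 and 0.178). OsIPS1 (Os03g0146800), a non-coding RNA of phosphate starvation, was at least 1.45-fold higher. Its fitted 1.21 ± 0.28 is uncertain in size, since no control array was well above background, and serves only to compare settings. Its call ended without control 6 h replicate 1 (1.01), without -P 6 h replicate 1 (1.24), without -P 6 h replicate 2 (1.04) and with normexp (0.34). It was called under -K at 6 h too, and did not differ by a call between -P and -K (-0.17 ± 0.28, adjusted p = 0.83).

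The largest rises under -P at 6 h were a nodulin 21 gene (Os04g0538400, 3.51 ± 0.27), the In2-1 protein gene (Os03g0283200, at least 2.19-fold) and a pathogenesis-related protein 1 gene (Os07g0127700, 2.26 ± 0.23). Falls among the ranked genes were those of a PM 19 membrane protein gene (Os05g0381400, -1.78 ± 0.36), of Os01g0871600 (-1.50 ± 0.19) and of a ZIP zinc transporter (Os05g0472400, -1.36 ± 0.22). By limma 1091 of 25513 genes were called, 668 higher and 423 lower, and 96 changed at least 2-fold, 72 higher and 24 lower. Normexp gave 407 higher and 526 lower, and 30 and 17 at 2-fold. The count fell to 223 with only the arrays compared, where Os05g0381400, Os05g0472400, OsIPS1, OsRR9 and OsRR10 were no longer called. It was 624 and 546 without control replicates 1 and 2, and 705, 714 and 592 without -P replicates 1, 2 and 3.

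The comparison of -K with the control at 6 h asked the same of potassium removal. Of 14 iron deficiency response genes 9 were lower and 5 were not called (13 lower adjusted over the list alone; camera adjusted p = 3.6e-11, and adjusted p = 0.053 with an estimated correlation). OsYSL2 (Os02g0649900), a transporter of chelated iron, changed by -1.52 ± 0.32, OsIRT2 (Os03g0667300) by -1.23 ± 0.12 and OsIRO2 (Os01g0952800) by -0.69 ± 0.13. The ferritins OsFER1 (Os11g0106700) and OsFER2 (Os12g0106000), at 0.03 ± 0.07 and 0.04 ± 0.08, were not called. Glutathione S-transferases were higher in 19 of 59 and not called in 40 (24 higher adjusted over the list alone; camera adjusted p = 6.14e-08, and adjusted p = 0.0166 with an estimated correlation), for example Os11g0125600 (0.55 ± 0.06) and Os03g0785900 (0.53 ± 0.06). Of 21 potassium transporters and channels 4 were higher, 1 was lower and 16 were not called (4 and 1 adjusted over the list alone). The transporter OsHKT2;1 (Os06g0701700) was higher by 0.80 ± 0.17 and the kinase OsCIPK23 (Os07g0150700) by 0.61 ± 0.07. That list call (camera adjusted p = 0.0243, and adjusted p = 0.0734 with an estimated correlation) ended with normexp (0.0613). Of 12 phosphate signalling genes 1 was higher and 11 not called. OsIPS1 (Os03g0146800) was at least 1.63-fold higher, a call lost with normexp (0.33). Its fitted 1.38 ± 0.28 is uncertain in size, since no control array was well above background.

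Of 14 nitrate uptake and reduction genes under -K at 6 h 7 were lower, 2 were higher and 5 were not called (7 and 3 adjusted over the list alone; camera adjusted p = 0.00793, and adjusted p = 0.304 with an estimated correlation). OsNRT2.1 (Os02g0112100), well above background on 1 of 3 -K and 2 of 3 control arrays, changed by -2.22 ± 0.29, its partner protein gene OsNAR2.1 (Os02g0595900) by -1.01 ± 0.11 and OsNRT1.1B (Os10g0554200) by -0.67 ± 0.09, and OsNPF6.3 (Os08g0155400) was higher by 0.63 ± 0.10. Of 9 ammonium transporters 3 were lower and 6 not called (4 lower adjusted over the list alone; camera adjusted p = 0.00946, and adjusted p = 0.19 with an estimated correlation), with OsAMT1;2 (Os02g0620500) at -0.99 ± 0.13 and OsAMT3;3 (Os02g0550800) at -0.53 ± 0.10. Ribosomal protein genes were higher in 14 of 298 and not called in 284 (4 higher adjusted over the list alone; camera adjusted p = 0.00078, and adjusted p = 0.748 with an estimated correlation). Of 6 tested genes of diterpenoid phytoalexin synthesis, which makes antimicrobial compounds, 2 were higher (3 adjusted over the list alone): OsCPS4 (Os04g0178300, 2.36 ± 0.52, well above background on 1 of 3 control arrays) and OsMAS (Os04g0179200, at least 5.99-fold). The call (camera adjusted p = 0.0254, and adjusted p = 0.303 with an estimated correlation) ended without a filter on dim probes (0.0725). Acid phosphatases were lower in 6 of 38 and higher in 1 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0296, and adjusted p = 0.406 with an estimated correlation), a call that ended with normexp (0.0692), quantile normalization (0.0733) and no filter (0.0725).

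The largest rise under -K at 6 h with a stable call was the water stress gene WSI76 (Os07g0687900, at least 13.9-fold). A germin-like protein gene (Os08g0460000) was at least 4.24-fold higher, but lost its call with normexp (1.88). LOB domain gene 30 (Os01g0772100, -1.97 ± 0.36) and the PM 19 gene (Os05g0381400, -1.97 ± 0.36) had the largest falls of the ranked genes, which leave out OsNRT2.1. By limma 3011 of 25513 genes were called, 1751 higher and 1260 lower, and 163 changed at least 2-fold, 122 higher and 41 lower. Normexp gave 1327 higher and 1441 lower, and 34 and 23 at 2-fold, and quantile normalization 1387 and 1509. The count fell to 584 with only the arrays compared, where Os08g0460000, Os05g0381400, Os01g0772100, OsYSL2, OsNRT2.1, OsAMT3;3 and OsHKT2;1 were no longer called. It was 1684 without control replicate 2 and 1857 and 1954 without -K replicates 2 and 3.

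**Figure D3:**
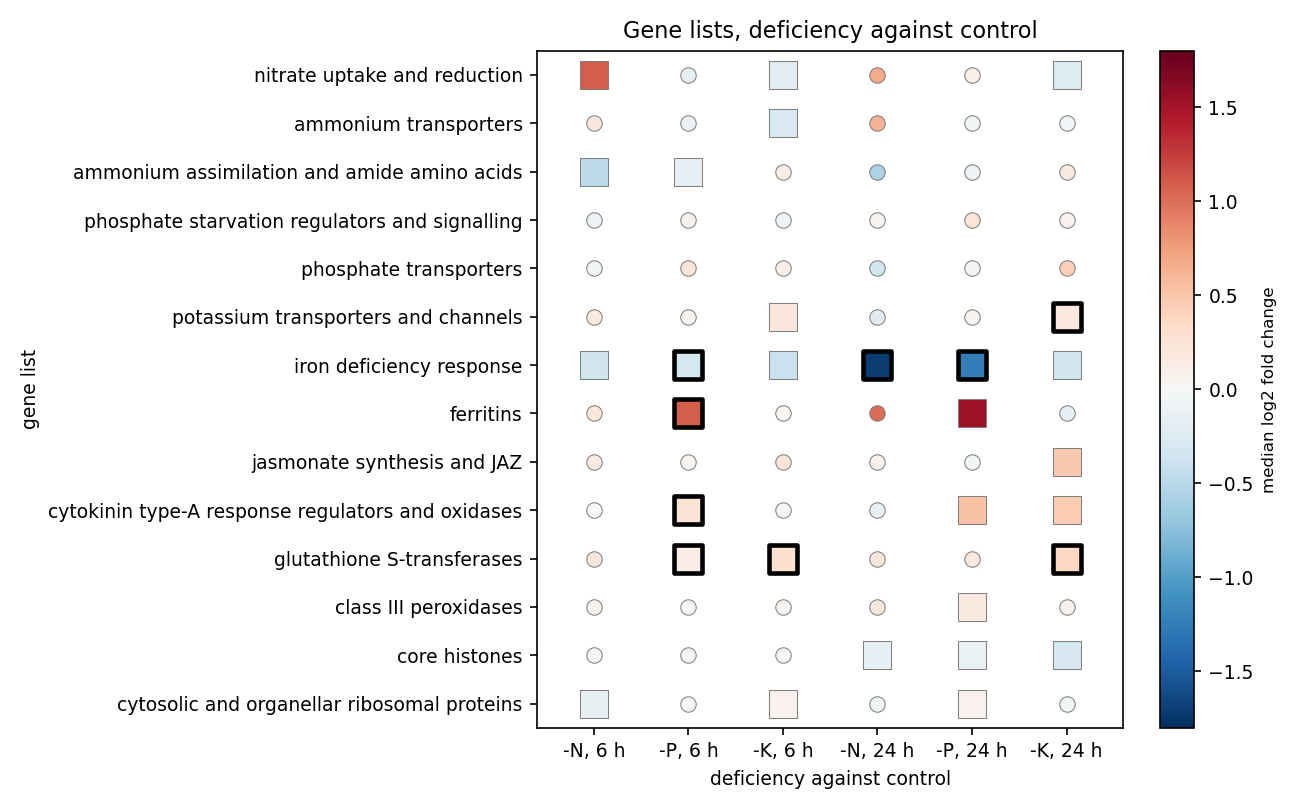
Median log2 fold change of 14 of the 30 gene lists (vertical axis) in the 6 comparisons of a deficiency with control (horizontal axis), shown as color. Squares mark camera calls at the preset correlation, heavy outlines those that held with an estimated correlation (for ferritins a test of 1 gene), and circles lists not called, and the largest median fall, -1.71, was that of the iron genes under -N at 24 h; medians of called lists drawn here kept their sign with normexp, quantile and series matrix values, while some near 0 of lists not called did not, such as phosphate signalling under -P at 6 h (0.08, with normexp -0.03).

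At 24 h of -N all 14 iron deficiency response genes were lower (14 adjusted over the list alone; camera adjusted p = 2.24e-13, and adjusted p = 0.0422 with an estimated correlation). OsIMA1 (Os01g0647200) changed by -3.47 ± 0.20, OsIRO3 (Os03g0379300) by -2.27 ± 0.09 and deoxymugineic acid synthase OsDMAS1 (Os03g0237100), which makes an iron chelator, by -1.94 ± 0.11. Ferritins OsFER2 (Os12g0106000) and OsFER1 (Os11g0106700) were higher by 1.05 ± 0.08 and 1.00 ± 0.08, OsFER1 from 2 -N arrays against 3 control arrays. Nitrate uptake and reduction genes went both ways, with 9 of 14 higher, 4 lower and 1 not called (9 and 4 adjusted over the list alone; camera adjusted p = 0.0611). OsNRT2.1 (Os02g0112100) was higher by 8.30 ± 0.29, OsNRT2.3 (Os01g0704100) by 3.41 ± 0.09 and OsNRT2.2 (Os02g0112600) by 1.89 ± 0.12. OsNRT1.1B (Os10g0554200), another nitrate transporter, changed by -4.51 ± 0.09. Of 9 ammonium transporters 5 were higher and 3 lower, with OsAMT1;2 (Os02g0620500) at 4.23 ± 0.13, OsAMT3;3 (Os02g0550800) at 1.96 ± 0.10 and OsAMT2;2 (Os01g0831300) at -4.57 ± 0.10. All 13 ammonium assimilation genes were called, 5 higher and 8 lower, with OsAlaAT (Os10g0390500) at -2.23 ± 0.09 and the glutamate synthase OsNADH-GOGAT2 (Os05g0555600) at least 5.15-fold higher.

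Of 6 fermentation and haemoglobin genes under -N at 24 h 2 were higher, 3 lower and 1 not called (2 and 4 adjusted over the list alone; camera adjusted p = 0.293). OsHB2 (Os03g0226200) changed by -7.15 ± 0.28 and OsHB1 (Os03g0233900) by -4.24 ± 0.19, and pyruvate decarboxylase OsPDC1 (Os05g0469600) was higher by 1.66 ± 0.10. Genes of reductant supply for nitrate assimilation were lower in 20 of 45, higher in 6 and not called in 19 (22 and 6 adjusted over the list alone; camera adjusted p = 0.00189, and adjusted p = 0.141 with an estimated correlation). Phenylpropanoid enzymes were higher in 17 of 36 and lower in 7 (18 and 7 adjusted over the list alone; camera adjusted p = 0.0254, and adjusted p = 0.5 with an estimated correlation). Aquaporins were lower in 6 of 14 and higher in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.039, and adjusted p = 0.603 with an estimated correlation), a call that ended without a filter (0.108), with normexp (0.363) and with quantile normalization (0.912), where the median of -0.17 became 0.003. Core histones were lower in 15 of 46 and higher in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 0.043, and adjusted p = 0.744 with an estimated correlation), a call that ended with normexp (0.649), quantile normalization (0.49) and no filter (0.19). Of 12 phosphate transporters 7 were lower and 1 higher, with OsPT8 (Os10g0444700) at -1.18 ± 0.14. The phosphate signalling gene OsIPS1 (Os03g0146800) was called lower. Its bound of 5.00-fold is no secure minimum, since only 1 of 3 control arrays was well above background. Of 21 potassium transporters and channels 10 were lower and 4 higher, with OsHAK4 (Os08g0466200) at -1.68 ± 0.20, and neither list was called.

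The largest other rises under -N at 24 h were a 1-deoxyxylulose phosphate synthase gene of plastid isoprenoid synthesis (Os07g0190000, 5.25 ± 0.63, well above background on 2 of 3 control arrays) and a patatin-like gene (Os08g0476900, at least 10.1-fold). The largest other falls were LOB domain gene 30 (Os01g0772100, -6.39 ± 0.36), the PM 19 gene (Os05g0381400, -6.16 ± 0.36), aldolase C-1 (Os08g0120600, -5.70 ± 0.24) and a plasma membrane proton ATPase gene (Os05g0319800, at least 14.4-fold lower). By limma 10795 of 25512 genes were called, 5736 higher and 5059 lower, and 2034 changed at least 2-fold, 1080 higher and 954 lower. Normexp gave 4258 higher and 8897 lower, and 475 and 940 at 2-fold. Against the mean of -P and -K, all scanned on day 2, 11007 genes were called, and the iron list was lower in 11 of 14.

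**Figure D4:**
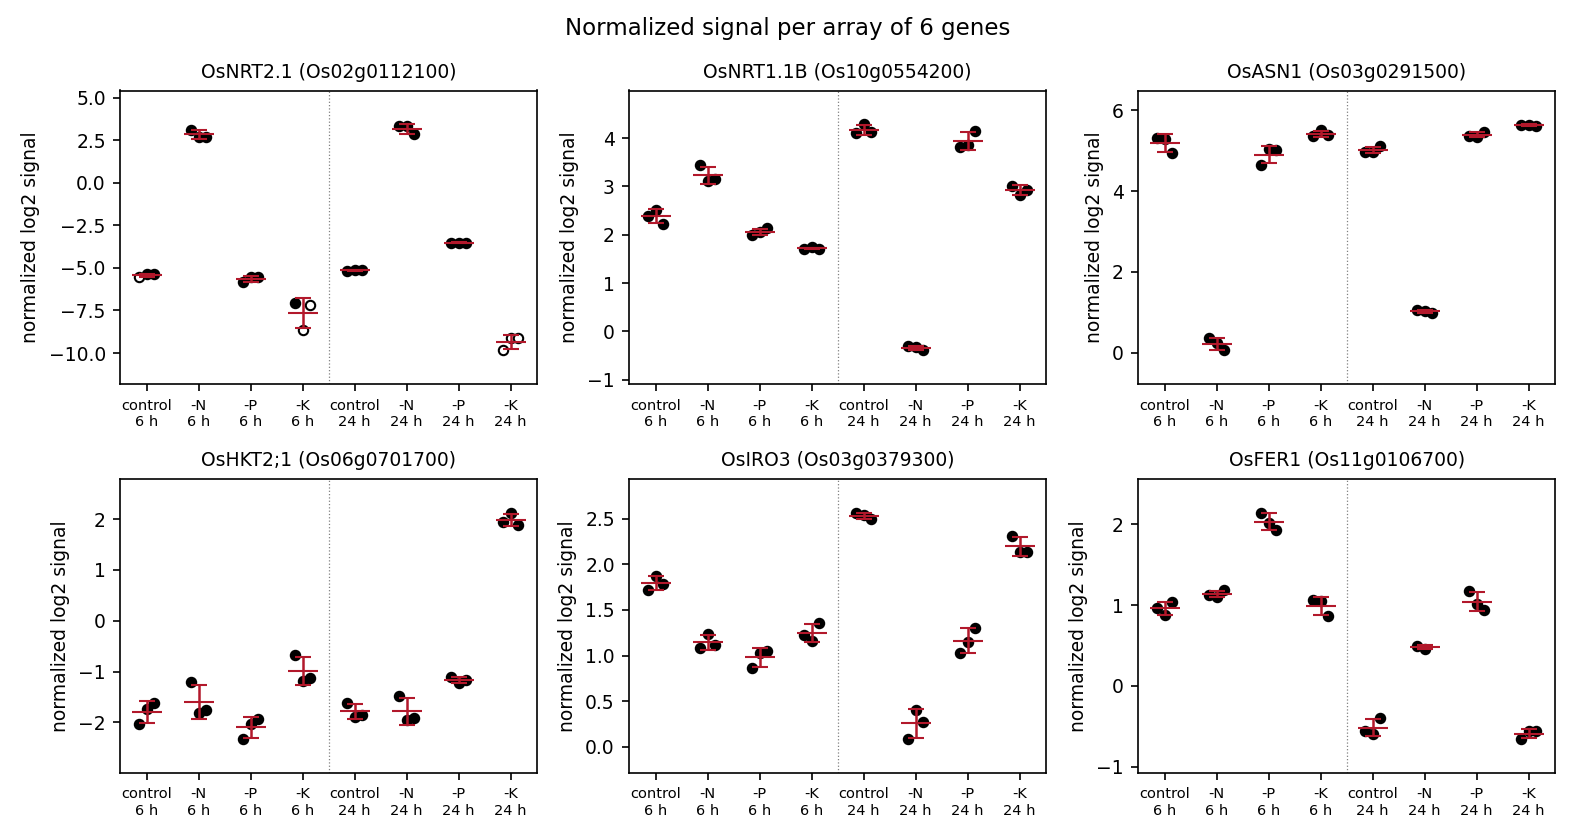
Normalized log2 signal (vertical axis) of 6 genes on each array, by group (horizontal axis): nitrate transporters OsNRT2.1 and OsNRT1.1B, asparagine synthetase OsASN1, the potassium and sodium transporter OsHKT2;1, the iron regulator OsIRO3 and ferritin OsFER1. Points are arrays, open where the signal was not well above background, and red bars are means with SD; OsNRT2.1 had a mean of -5.42 in the 6 h control and 2.84 under -N at 6 h, and OsHKT2;1 -1.78 in the 24 h control and 1.98 under -K at 24 h.

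At 24 h of -P all 14 iron deficiency response genes were lower (14 adjusted over the list alone; camera adjusted p = 8.77e-21, and adjusted p = 0.0166 with an estimated correlation), and both ferritins were higher, OsFER1 (Os11g0106700) by 1.56 ± 0.07 and OsFER2 (Os12g0106000) by 1.52 ± 0.08. OsIRT2 (Os03g0667300) changed by -1.46 ± 0.12, OsIRO3 (Os03g0379300) by -1.37 ± 0.09, OsDMAS1 (Os03g0237100) by -1.32 ± 0.11 and the iron transporter OsYSL15 (Os02g0650300) by -0.96 ± 0.06. Class III peroxidases were higher in 31 of 119, lower in 3 and not called in 85 (35 and 6 adjusted over the list alone; camera adjusted p = 0.000198, and adjusted p = 0.21 with an estimated correlation), for example Os07g0531400 (2.08 ± 0.17) and Os06g0521500 (1.29 ± 0.14). Cytokinin response genes were higher in 6 of 9 and lower in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00515, and adjusted p = 0.053 with an estimated correlation). OsRR9 (Os11g0143300) was higher by 0.62 ± 0.09, and the cytokinin oxidase OsCKX5 (Os01g0775400) changed by -1.31 ± 0.12. Ribosomal protein genes were higher in 35 of 298 and lower in 2 (23 and 2 adjusted over the list alone; camera adjusted p = 0.00245, and adjusted p = 0.751 with an estimated correlation).

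Phosphate signalling genes under -P at 24 h were higher in 4 of 12, lower in 1 and not called in 7 (5 and 2 adjusted over the list alone; camera adjusted p = 0.199), with a median of 0.23 that became -0.01 with normexp. The sensor proteins OsSPX6 (Os07g0614700) and OsSPX1 (Os06g0603600) were higher by 0.71 ± 0.13 and 0.54 ± 0.05. Of 12 phosphate transporters 1 was higher, OsPT2 (Os03g0150800) at 0.85 ± 0.15, and 1 was lower, with a median of 0.02 that became -0.19 with normexp (camera adjusted p = 0.785). OsNRT2.1 (Os02g0112100) was higher by 1.61 ± 0.29, and OsNADH-GOGAT2 (Os05g0555600) was at least 2.45-fold higher, a call lost with normexp (0.50). OsJAZ9 (Os03g0180800), a jasmonate repressor, changed by -2.33 ± 0.17. Calls of lower reductant supply genes (11 of 45 lower, 2 higher, and 11 and 2 adjusted over the list alone), core histones (5 of 46 lower, 2 higher, and 3 and 2 adjusted over the list alone) and WRKY factors (13 of 65 lower, 5 higher, and 14 and 5 adjusted over the list alone) had camera adjusted p = 0.0254, 0.0099 and 0.043, and adjusted p = 0.304, 0.728 and 0.523 with an estimated correlation. These 3 calls ended with normexp (0.31, 0.672 and 0.0793), quantile normalization (0.0535, 0.123 and 0.0669) and no filter (0.202, 0.137 and 0.137).

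The largest other rises under -P at 24 h were those of the nodulin 21 gene (Os04g0538400, 4.15 ± 0.27) and of the ASC1 gene Os02g0728300 (4.71 ± 0.95, a call lost with only the arrays compared). Falls were those of an acid phosphatase gene (Os01g0191200, -4.57 ± 0.37), LOB domain gene 30 (Os01g0772100, -3.97 ± 0.36) and an F-box gene (Os08g0195800, at least 20.6-fold lower). By limma 5220 of 25512 genes were called, 2794 higher and 2426 lower, and 646 changed at least 2-fold, 302 higher and 344 lower. Normexp gave 1812 higher and 5941 lower, and 76 and 326 at 2-fold. The count was 3416 without -P replicate 2 and 2949 with only the arrays compared. Against the mean of -N and -K on the same scan day 4558 genes were called, ferritins were higher in 2 of 2, and 3 of 14 iron list genes were lower.

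At 24 h of -K potassium transporters and channels were higher in 9 of 21, lower in 1 and not called in 11 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00078, and adjusted p = 0.0166 with an estimated correlation). OsHKT2;1 (Os06g0701700) was higher by 3.76 ± 0.17, OsHKT1;1 (Os04g0607500) by 3.31 ± 0.27, OsCIPK23 (Os07g0150700) by 1.22 ± 0.07 and OsHAK7 (Os07g0669700) by 0.75 ± 0.06. Glutathione S-transferases were higher in 29 of 59 and lower in 4 (33 and 4 adjusted over the list alone; camera adjusted p = 5.3e-07, and adjusted p = 0.0202 with an estimated correlation), with Os09g0367700 at 3.88 ± 0.35 and Os01g0558100 at 1.34 ± 0.11. Jasmonate synthesis and repressor genes were higher in 12 of 17 and lower in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 4.2e-05, and adjusted p = 0.121 with an estimated correlation). The synthesis enzyme OsAOS2 (Os03g0225900), well above background on 2 of 3 control arrays, was at 2.61 ± 0.29 and the repressors OsJAZ11 (Os03g0180900) and OsJAZ10 (Os03g0181100) at 1.42 ± 0.14 and 0.98 ± 0.09. Core histones, which package newly made DNA, were lower in 34 of 46 and higher in 1 (38 and 1 adjusted over the list alone; camera adjusted p = 5.98e-10, and adjusted p = 0.368 with an estimated correlation). Examples were an H3 gene (Os06g0160100, -0.65 ± 0.08), an H2A gene (Os05g0113900, -0.59 ± 0.09) and an H4 gene (Os01g0835900, -0.40 ± 0.05).

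Sulfate transport and assimilation genes were higher in 9 of 19 and lower in 1 under -K at 24 h, in a solution without potassium sulfate, where the labels did not say whether the sulfate was replaced (10 and 2 adjusted over the list alone; camera adjusted p = 0.0127, and adjusted p = 0.053 with an estimated correlation). A sulfate transporter gene (Os01g0719300) was 4.93-fold higher and a serine acetyltransferase (Os01g0720700) higher by 0.89 ± 0.09. Cytokinin response genes were higher in 6 of 9 and lower in 1 (7 and 1 adjusted over the list alone), with OsRR9 (Os11g0143300) at 0.71 ± 0.09, a call (camera adjusted p = 0.0099, and adjusted p = 0.0734 with an estimated correlation) that ended without a filter (0.0618). Fermentation and haemoglobin genes were higher in 4 of 6 (4 adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.312 with an estimated correlation). OsPDC1 (Os05g0469600) was higher by 0.96 ± 0.10, or 0.26 and not called with the mean of its probes, and alcohol dehydrogenase OsADH1 (Os11g0210300) by 0.69 ± 0.13. Of 4 markers of endodermis and exodermis 3 were lower (3 adjusted over the list alone), OsCASP1 (Os04g0684300) of the Casparian strip at -0.76 ± 0.10 and the silicon transporters OsLsi2 (Os03g0107300) and OsLsi1 (Os02g0745100) at -0.66 ± 0.10 and -0.56 ± 0.08. Their call (camera adjusted p = 0.0218, and adjusted p = 0.303 with an estimated correlation) ended with normexp (0.121) and no filter (0.0507). Of 12 phosphate transporters 5 were higher and 7 not called, with OsPT3 (Os10g0444600) at 1.54 ± 0.22 and OsPT8 (Os10g0444700) at 1.27 ± 0.14 (camera adjusted p = 0.135).

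Of 14 nitrate uptake and reduction genes under -K at 24 h 6 were lower, 2 higher and 6 not called (6 and 2 adjusted over the list alone), and of 13 ammonium assimilation genes 4 were lower, 6 higher and 3 not called. OsNRT2.1 (Os02g0112100) was at least 8.22-fold lower, with OsNAR2.1 (Os02g0595900) at -1.51 ± 0.11, OsNRT1.1B (Os10g0554200) at -1.25 ± 0.09 and nitrite reductase OsNiR2 (Os02g0765900) at -0.96 ± 0.07, and OsAMT3;3 (Os02g0550800) changed by -2.19 ± 0.10. Reductant supply genes were lower in 18 of 45 and higher in 3 (18 and 3 adjusted over the list alone), and iron deficiency response genes lower in 9 of 14 and higher in 1 (9 and 1 adjusted over the list alone). OsIRO2 (Os01g0952800) changed by -0.95 ± 0.13 and OsIRT2 (Os03g0667300) by -0.76 ± 0.12. The calls of the nitrate, reductant and iron lists (camera adjusted p = 0.0291, 0.0296 and 0.00189) had adjusted p = 0.406, 0.312 and 0.406 with an estimated correlation. They ended with normexp (0.177, 0.217 and 0.0613), the nitrate call also with quantile normalization (0.061) and no filter (0.0948) and the reductant call with no filter (0.137). The largest other rises were the ASC1 gene (Os02g0728300, 4.08 ± 0.95) and a germin-like gene (Os08g0460000, at least 4.32-fold higher, a call lost with normexp at 1.71). Falls were those of the F-box gene Os08g0195800 (-4.61 ± 0.51, well above background on 1 of 3 -K arrays) and of a 10 kDa prolamin gene (Os03g0766100, at least 6.12-fold).

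By limma 9059 of 25510 genes were called under -K at 24 h, 4528 higher and 4531 lower, and 996 changed at least 2-fold, 768 higher and 228 lower. Normexp, which moved the median of all genes by -0.10, gave 3235 higher and 8111 lower, and 270 and 188 at 2-fold. Against the mean of -N and -P on the same scan day 11075 genes were called, potassium transporters were higher in 13 of 21, core histones lower in 31 of 46 and all 14 iron list genes higher, the reverse of the fall of this list against the control.

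The comparisons between deficiencies at 6 h, within scan day 1, asked which changes differed between nutrients. OsNRT2.1 (Os02g0112100) was higher under -N than under -P by 8.48 ± 0.29 and than under -K, where 1 of 3 arrays was well above background, by 10.47 ± 0.29, and the osa-miR166m precursor by 4.55 ± 0.15 and 4.76 ± 0.15. OsASN1 (Os03g0291500) was lower under -N than under -P (-4.69 ± 0.10) and than under -K (-5.20 ± 0.10), and aldolase C-1 (Os08g0120600) lower than under -K (-6.49 ± 0.24). The nodulin 21 gene (Os04g0538400) was higher under -P than under -K by 4.60 ± 0.27, and an alpha-amylase gene (Os08g0473900) at least 3.15-fold higher. The F-box gene Os08g0195800 was at least 2.32-fold lower under -P than under -K. Limma called 9499 genes between -N and -P (5234 higher under -N, 4265 lower), 11017 between -N and -K (5558 and 5459) and 1410 between -P and -K (610 higher under -P, 800 lower). The count between -P and -K was 203 with only the arrays compared, 267 within the 1 slide that held both groups (with 1 -P array, against 3 -K arrays, so that it tests little), 871 without -P replicate 2, and 928 and 877 without -K replicates 2 and 3.

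The same comparisons at 24 h stayed within scan day 2. OsNRT2.1 (Os02g0112100) was higher under -N than under -P by 6.69 ± 0.29, at least 2584-fold higher than under -K, and at least 25.1-fold higher under -P than under -K. The plastid isoprenoid gene Os07g0190000 was higher under -N than under -P by 4.99 ± 0.63, and allantoinase (Os04g0680400), which breaks down stored nitrogen, higher than under -K by 5.09 ± 0.13. OsHB2 (Os03g0226200) was lower under -N than under -K (-8.13 ± 0.28), and aldolase C-1 (Os08g0120600) lower than under -P (-6.21 ± 0.24) and -K (-8.06 ± 0.24). A pathogenesis-related protein 1 gene (Os07g0129300) was lower under -N than under -P (-6.58 ± 0.44), the nodulin 21 gene (Os04g0538400) higher under -P than under -K (4.91 ± 0.27), and the acid phosphatase gene Os01g0191200 lower (-5.03 ± 0.37). Limma called 7692 genes between -N and -P (3941 higher under -N, 3751 lower), 12109 between -N and -K (6421 and 5688) and 7327 between -P and -K (3863 higher under -P, 3464 lower).

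In the controls, 24 h against 6 h, within scan day 1, the circadian clock list changed: 1 of 9 genes was higher, 7 were lower and 1 was not called (1 and 7 adjusted over the list alone; camera adjusted p = 4.61e-07, and adjusted p = 0.00917 with an estimated correlation). OsLHY (Os08g0157600), a morning regulator, was higher by 3.24 ± 0.08, and the evening genes OsPRR95 (Os09g0532400), OsPRR1 (Os02g0618200) and OsGI (Os01g0182600) changed by -3.71 ± 0.10, -2.43 ± 0.07 and -1.84 ± 0.07. Cytokinin response genes were higher in 7 of 9 (camera adjusted p = 0.000191, and adjusted p = 0.00984 with an estimated correlation). Iron deficiency response genes were higher in 10 of 14 and lower in 1, with a mean of 0.532 (camera adjusted p = 0.000895, and adjusted p = 0.288 with an estimated correlation). Ferritins were lower in 2 of 2, with a mean of -1.485. Limma called 9049 genes, 4755 higher and 4294 lower. The hour of day of sampling was not given.

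Whether an effect differed between 24 h and 6 h was tested as an interaction, in which the 24 h effect set scan day 2 against day 1. The fall of the iron deficiency response genes against the control was larger at 24 h than at 6 h under -N (mean difference -1.28, 13 of 14 genes) and under -P (-0.64, 8 of 14), each with camera adjusted p = 2.16e-13 and adjusted p = 0.0478 with an estimated correlation. Part of each difference came from the control, where the list rose between the times (mean 0.532). Under -P the slide means of the list were 2.297 and 2.305 at 6 h and 2.023 and 2.275 at 24 h. Under -K potassium transporters (mean difference 0.34, 6 of 21 genes) and cytokinin response genes (0.34, 5 of 9) were higher at 24 h than at 6 h, with camera adjusted p = 0.0022 and 0.00113 and adjusted p = 0.0478 for both with an estimated correlation. Limma called 5454 genes for -N, 928 for -P and 2285 for -K. The -P split of 358 higher and 570 lower was 314 and 1266 with normexp, and the -K split of 1144 and 1141 was 1020 and 2291. The -P count was 607 with only the arrays compared and 591 without 24 h control replicate 2, and the -K count 1217 without -K 24 h replicate 1 and 1487 without 24 h control replicate 2.

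Calls shared by the 3 deficiencies numbered 283 higher and 134 lower at 6 h, and 1032 higher and 760 lower at 24 h, where all 3 shared the scan day difference to the control. At 24 h -N and -P shared 1850 higher and 1653 lower calls, where independent calls would share 625.2 and 478.9, and 209 genes were called in opposite directions. At 24 h -N and -K shared 1623 higher and 1385 lower calls with 1893 opposite, and -P and -K shared 1523 and 1167 with 353 opposite. All pairs share their control arrays: in groups simulated without any change the correlation of effects across genes was 0.501 for -N and -P at 24 h, against 0.586 measured, and the covariance 0.0187 against 0.146. For -N and -K the simulated correlation was 0.502 against 0.201 measured, and for -P and -K 0.502 against 0.486. The covariances of these pairs were 0.0187 against 0.0595 and 0.089. The simulated groups held no effects, so that their correlation came from the shared controls alone. It is no reference for groups with large effects. The measured covariance exceeded the simulated one for each pair at 24 h, where the scan day difference to the control was shared too.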

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

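The tests of lower background, of shared control arrays, of scan day for the iron genes, of ferritins and of random assignment without time and deficiency effects were chosen only after the results they bear on had been seen. Time differences were singled out because a direct test found the effect of a deficiency at 24 h to differ from that at 6 h. The iron deficiency response list had a mean difference of -1.28 under -N and -0.64 under -P, and under -K potassium transporters and channels had 0.34 and cytokinin response regulators and oxidases 0.34. The iron differences include a rise of that list in the controls between the times (mean 0.532). Single genes with the largest differences under -N were the deoxyxylulose phosphate synthase Os07g0190000 (5.63 ± 0.89), the ent-kaurene oxidase Os06g0569500 (5.12 ± 1.29), the proton ATPase Os05g0319800 (-6.13 ± 0.66) and the F-box gene Os08g0195800 (-5.86 ± 0.73). Under -P they were OsNADH-GOGAT2 (Os05g0555600, 2.63 ± 0.28, or 0.82 and not called with normexp), Os08g0195800 (-5.32 ± 0.73) and an actin gene (Os12g0641000, -3.63 ± 0.25). Under -K they were a GDSL lipase gene (Os10g0393800, 3.61 ± 0.61), the cation transporter gene Os04g0607600 (3.59 ± 0.45), Os08g0195800 (-7.62 ± 0.73) and the prolamin gene Os03g0766100 (-4.47 ± 0.79). Except for the actin gene, each had a group that was not well above background on its 3 arrays, so that the size of the difference is uncertain.

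The numbers of genes with a time difference were 5454 for -N, 928 for -P and 2285 for -K. Splits of the same 12 arrays into 4 groups at random called as many in 1, 9 and 9 of 100, the real grouping counted among them, with highest other counts of 5016, 5762 and 5917. These say nothing about chance, since the arrays also differed by time (9049 genes between the controls) and by deficiency (10795, 5220 and 9059 genes at 24 h), a structure of the samples that the splits leave in. In a random assignment without time and deficiency effects, of the residuals of a fit with both over 25357 genes, as many genes were called in 1, 2 and 1 of 100 for -N, -P and -K, again with the real grouping among them, so that 0, 1 and 0 random assignments did. The real counts there were 5417, 921 and 2272 and the highest others 994, 2812 and 89. For -N and -K a random grouping of arrays may thus be set aside, but not a grouping by slide or scan day. For -P the 1 assignment with 2812 genes, several times the real count, points to a structure among the residuals of the arrays. Its share of 2 of 100 therefore decides nothing. Scan day stays confounded with each 24 h effect.

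Random-sequence probes, left out of the gene tests, were singled out because they differed between groups although they match no rice gene. They were well above background for 11.4%, 7.78% and 7.22% of probes under -N, -P and -K at 6 h and 30.6%, 26.9% and 36.4% at 24 h, against 1.67% and 2.5% in the controls. Part of this may come from the lower background of scan day 2, and the 3 arrays that stood apart could have another, unknown origin; the cause was not tested.

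At 24 h 1792 genes were called the same way in all 3 deficiencies against a control scanned on another day. A lower background on day 2 could move dim genes most. Of the 1792, 70.4% lay above a normalized log2 level of -4 against 72.6% of the other genes, which decides nothing. Those that changed at least 2-fold in all 3 deficiencies were dimmer, with median levels of -6.46 for rises and -6.31 for falls. The medians for all shared rises and falls were -2.74 and -1.02. Genes below a level of -6 had median changes of 0.22, 0.128 and 0.242 under -N, -P and -K at 24 h. Above a level of 0 the medians were -0.04, -0.01 and -0.037. Dim genes thus rose in the median, while negative controls moved by -1.99, -1.81 and -1.88. Dim probes could pass the filter through a day 2 group alone, which may favor rises, so that these medians cannot decide. The larger shared changes lay among dim genes, and this cause stays open. At 6 h, within day 1, the 14 shared 2-fold rises were dim too (median level -5.76), and the 4 shared falls were not (-1.12). For scan day as the whole cause, 86.3% had the same sign at 6 h, within day 1, against 65% of other genes. This cannot decide, since the 6 h deficiency arrays also differed from their controls in signals that match no rice gene. Negative controls moved by -0.545, -0.496 and -0.436 under -N, -P and -K at 6 h, and further down at 24 h. A technical difference in the same direction at both times could give the same signs. Noise of the shared control arrays gave 0 such genes in simulated groups. Those groups held no effects, so that few genes could be called at all. The simulation therefore cannot say how much control noise adds where many genes are called. A response to the change of solution itself would be shared by the control, which was changed too. It would not be expected to give these genes, but this was not tested. Scan day stays open as a cause.

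The lower iron deficiency response genes under -P and -K at 6 h, such as OsIRT2 (Os03g0667300), could come from slides or more iron reaching the root, and not from scan day, since all 6 h arrays were scanned on day 1. The largest difference between slides of a group was 0.252, under -P at 24 h, just under the limit of 0.268 set from the smaller fall. At 6 h it was 0.121 in the control and 0.008 under -P. This cannot settle slides as a cause, since no slide held both a control and a deficiency. More iron would be expected to raise ferritins, and limma called 0 of 2 higher under -K at 6 h, with 0 at an unadjusted p under 0.05, against 2 under -P, and 2 of 2 were higher under -P than under -K in a direct limma comparison. More iron is thus argued against for -K, and for -P it may hold. Both ferritins had the same description and close levels, OsFER2 1.125 and OsFER1 0.961 in the 6 h control. Cross-hybridization between the 2 ferritins was not tested, so that they may not be separate measurements. At 24 h the list mean was 0.992 higher under -K than under -N and -P within day 2, so that scan day may not be the whole cause there.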

How the results depend on the processing

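The fit without 3 arrays that stood apart and the comparison with the mean of the other 2 deficiencies were chosen only after results had been seen. All 22 counts of genes stayed within 1.5-fold with quantile normalization, series matrix values, slide as a random block, a replicate block (for -N at 6 h 10409), eBayes with trend and robust setting, outlier marks ignored and the mean of the probes of a gene, and 12 of 12 without the 3 arrays. Of 41 list calls all held with series matrix values, slide block and replicate block. With quantile normalization 33 held, without a filter 30 and with normexp 28. With an estimated correlation 9 held, and 36 with fry, which does not compare with other genes. The series matrix holds the same signals less a constant per array, so that its agreement in counts and lists tests little. The slide block had a consensus correlation of -0.0207. Most slides held only 1 group, so that this block could not remove slide differences between groups. Over all 180 tests 9 lists were called with an estimated correlation and 90 with fry. Of 215 pairs of named gene and contrast, 208 kept their call with normexp, 213 with the mean of probes and 198 with only the arrays compared. Depth limits the sizes: of the genes changed 2-fold, 869 of 1323, 60 of 96 and 71 of 163 for -N, -P and -K at 6 h and 1370 of 2034, 366 of 646 and 489 of 996 at 24 h were well above background in both groups. Where a count moved by more than 1.5-fold, the cause was not tested. With normexp the 2-fold counts were 831, 47 and 57 for -N, -P and -K at 6 h and 402 and 458 for -P and -K at 24 h, and 1580 genes had a time difference under -P. With only probes well above background on all 24 arrays the 2-fold counts were 864, 57 and 66 at 6 h and 1252, 306 and 413 at 24 h, and without a filter 4277, 2689 and 2962 at 24 h. With only the arrays compared 223 genes were called for -P and 584 for -K at 6 h (60 and 95 at 2-fold), 2949 for -P at 24 h, 203 between -P and -K at 6 h and 607 for the -P time difference. Slide as a fixed block, which is the same as within the 1 shared slide, gave 267 between -P and -K at 6 h, from 1 -P array and 3 -K arrays, too few to test the count. Leaving out 1 array gave 546 to 742 genes for -P and 1684 to 2378 for -K at 6 h, 3416 to 5145 for -P at 24 h, 871 to 1117 between -P and -K at 6 h, and 591 to 898 and 1217 to 2102 for the -P and -K time differences; OsFER1 (Os11g0106700), not called for -K at 6 h, was -0.0104 without 6 h control replicate 2, -0.0034 without -K replicate 1 and at most 0.0948, without -K replicate 3.

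Against the mean of the other 2 deficiencies, which shifts the reference from the control and so tests something else, 417 genes changed 2-fold under -P at 24 h. Signs turned for core histones under -N (adjusted p = 0.0831) and -P (adjusted p = 0.000556), iron genes under -K (adjusted p = 1.19e-08) and reductant supply under -K (adjusted p = 0.504) and -P (adjusted p = 0.0561) by camera. Under -P they turned for Os08g0460000 (-0.64), Os04g0644400 (-0.45), Os08g0476900 (-1.29), Os03g0766100 (0.44), Os05g0555600 (-0.28) and Os02g0112100 (-0.43). Under -K they turned for Os02g0728300 (-0.12), Os08g0460000 (-0.33), Os10g0554200 (1.12), Os05g0469600 (-0.12), Os01g0952800 (0.58) and Os03g0667300 (0.88).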

Other observations

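The test of scan day for the histones was chosen only after the result was seen. Lists without a camera call in a comparison with the control could still hold many called genes. Expansins, which loosen cell walls, were lower in 13 of 39 and higher in 5 under -N at 24 h. Chitinases and pathogenesis-related proteins were lower in 34 of 94 and higher in 20 under -N at 24 h, and higher in 27 and lower in 14 under -K at 24 h, where normexp turned the median to -0.02. Heat shock proteins were higher in 35 of 114 and lower in 10 under -K at 24 h (camera adjusted p = 0.0937), where normexp turned the median to -0.03. Galactolipid synthesis genes and phospholipases, which replace membrane phospholipids in phosphate shortage, were higher in 3 of 30 and lower in 6 under -P at 24 h. Of 4 ACC oxidases, which make ethylene, 2 were called higher under -K and 2 lower under -N at 24 h, but 1 of the 2 was each time not well above background in the control, so that only 1 gene had a measured direction. Acid phosphatases were higher in 8 of 38 and lower in 5 under -P at 24 h (camera adjusted p = 0.985), with a median of 0.02 that became -0.06 with normexp. Circadian clock genes were higher in 4 of 9 and lower in 1 under -N at 24 h.

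Jasmonate synthesis and repressor genes parted between deficiencies within scan day 2. Against the mean of the other 2 deficiencies at 24 h, 13 of 17 were higher and 1 lower under -K (camera adjusted p = 1.69e-05, and adjusted p = 0.103 with an estimated correlation), and 13 were lower and 1 higher under -P (camera adjusted p = 8.14e-08, and adjusted p = 0.0598 with an estimated correlation). Potassium transporters were higher in 13 of 21 and lower in 2 under -K (camera adjusted p = 0.00014, and adjusted p = 0.0223 with an estimated correlation).

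Fewer replicating cells under -K at 24 h could explain the lower core histones, and scan day or cross-hybridization within 1 histone family could too. Scan day as the whole cause is argued against by a median of -0.227 against -N and -P within day 2. Medians of H4, H3, H2A and H2B genes were -0.40, -0.36, -0.32 and -0.16, and 3 of 4 families passed the limit set for the test. This argues against cross-hybridization within 1 family alone. Cross-hybridization among the similar genes inside each family was not tested, so that the 46 genes may not be separate measurements. Falls of this size against the control depend on the scale, on which 7 bright spike-in controls moved by -0.52 under -K at 24 h, and by -0.56 and -0.50 under -N and -P. Genes picked by DNA replication terms in their description had a median of -0.209 under -K, with 19 of 43 called lower and 1 higher, and -0.17 within day 2. The match also took in genes that may not serve replication. Among them were a DNA topoisomerase III gene (Os09g0500600, -0.381) and a ferritin or ribonucleotide reductase-like gene (Os03g0713600, -0.363), both called lower. The lower medians could fit less DNA replication in the root, a hypothesis that cell counts could test.

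Splitting 3 against 3 arrays in other ways gives 10 splits, too few for a permutation share under 0.05. In each of the 19 counts tested the real split was the highest, 1 of 10. No slide held both a control and a deficiency, and at 24 h these also differed by scan day. A slide or scan day difference could therefore give the same outcome, and the splits cannot tell it from a deficiency. Against the control at 6 h the real counts were 10731 for -N, 1091 for -P and 3011 for -K, and the highest others 0, 74 and 3. At 24 h the real counts were 10795, 5220 and 9059, and the highest others 1, 0 and 2. At 2-fold the real counts were 1323, 96 and 163 at 6 h and 2034, 646 and 996 at 24 h, and the highest others 0, 11 and 2, and 1, 0 and 1. Between -N and -P, -N and -K, and -P and -K the real counts were 9499, 11017 and 1410 at 6 h and 7692, 12109 and 7327 at 24 h, and the highest others 2, 0 and 1, and 2, 1 and 5. Between the controls 9049 genes were called and at most 3 in another split.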
